A study of Mus musculus with 5 samples.

How the data were processed

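Single-cell RNA sequencing libraries of CD45-positive cells from flank tumours were compared, 3 from tumours of Scramble cells and 2 from tumours of JAG2KO cells, with groups and replicate numbers taken from the labels. The deposited matrices hold raw UMI counts per gene and barcode, and per the file headers the authors made these counts with cellranger 6.0.0. The submitters' processing notes name Seurat and the mouse genome GRCm38 (mm10) without saying what each was used for. Per the labels, barcodes without a cell were removed before deposit. Each matrix lists 32285 genes. No reads, protein measurements or measures of tumour size were used here.

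Barcodes with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs were kept. Doublet scores were computed with an implementation of the Scrublet method, and the 8% of cells with the highest scores were removed from each library. Over 10% mitochondrial UMIs were found in 1555, 2060 and 2036 barcodes of the Scramble libraries and 2433 and 2511 of the JAG2KO libraries, and 17, 7, 33, 77 and 544 barcodes had under 250 genes. Cells of the 5 libraries were clustered together on 50 principal components of 2000 variable genes with 20 neighbours and the Leiden method at a resolution of 1.5, which gave 34 clusters. Lymphoid cells were clustered again on 20 components of 1000 genes with 15 neighbours. Clusters were named by marker lists fixed before the data were examined, with a score of at least 0.3, 3 detected markers and no more markers of another class than of their own among their 10 leading genes, and a class named in this way is written as macrophage-like and so on. The score of 0.5 asked of lymphoid sub-clusters was set after seeing the data. Named alike by joint and separate clustering were 80.2% of cells.

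For gene expression, UMIs were summed per library over monocytes and macrophages, neutrophils, dendritic cells, CD4 T cells with regulatory T cells, and NK cells. The library was the replicate, a library with fewer than 20 cells of a class was left out, and a class needed 2 libraries per group, so CD8 T-like and B-like cells were not tested. JAG2KO was compared with Scramble by the quasi-likelihood test of edgeR 4.0.16 with TMM scaling and its filter on low counts, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Shares of cells were compared by edgeR on cell numbers with the total of kept cells as offset, and by a two-sided exact permutation test, for which 10 splits exist and 0.1 is the smallest p. Every adjusted p of a gene or a share comes from edgeR and every adjusted p of a list from camera in limma 3.58.1, unless another tool is named. Intervals of shares and of Jag2 are exact 95% intervals (Clopper-Pearson for shares, Poisson for Jag2) and cover counting error only, as does the limit of 3 counts used for a count of 0.

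The 24 gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternatives. They cover the Notch pathway, MHC class II, MHC class I, type I interferon response, interferon gamma response, co-stimulation and stimulatory cytokines, alternative activation and suppression, complement and tissue macrophage genes, monocyte genes, myeloid transcription factors, chemokines, hypoxia and glycolysis, lipid handling, neutrophil maturation, tumour-associated neutrophils, cytotoxicity, T cell exhaustion, naive and memory T cells, regulatory T cells, dendritic cell maturation, cell cycle, dissociation and stress, cytosolic ribosomal proteins and mitochondrially encoded genes. A list needed 5 measured members. Lists were compared with all other genes by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry, which tests a list by itself. Calls by fry are those for movement in a common direction.

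Named genes are those past the threshold with a mean of at least 10 CPM and with both JAG2KO libraries on the same side of all 3 Scramble libraries, the 10 largest changes each way in monocytes and macrophages and 3 each way in the other classes. Immunoglobulin and T cell receptor segments, haemoglobins, mitochondrial and ribosomal protein genes, sex-linked markers and unnamed gene models were left out of this part. Up to 4 members of each list with the smallest adjusted p could be named too, and in monocytes and macrophages Notch1, Notch2, Rbpj, Hes1, Dll1, Dll4, Jag1, Irf4, Arg1, Mrc1, Cd274, Cxcl9 and H2-Ab1 in any case. In a class without a called gene the 3 smallest p-values were named.

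Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, cells of at least 1000 UMIs and 500 genes, at most 5% mitochondrial UMIs, doublets kept or removed by the automatic threshold, separate clustering of each library, sums thinned to the smallest library, genes under 10% of their level in another class left out, the replicate number as a block, and each library left out in turn. Where this left a group with 1 library, that library was assumed to vary like the others. Subsets of classes, clusters with over 90% of cells from 1 library left out, named immune cells as the total, and a lymphoid score of 0.3 with and without the rule on leading genes were added after seeing the data. On simulated data with 100 genes changed 2-fold, edgeR recovered 71 in monocytes and macrophages, 34 in neutrophils, 75 in dendritic cells, 42 in CD4 T cells and 40 in NK cells, and at 4-fold 92, 77, 94, 91 and 90. False calls were 10 of 173 calls in monocytes and macrophages, 7 of 118 in neutrophils and 19 of 188 in dendritic cells. They were 2 of 135 in CD4 T cells and 11 of 141 in NK cells. The simulated groups had the same spread. Computations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3.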

Results

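Tumours grown in the flanks of mice from Lewis lung carcinoma cells, a mouse lung cancer line, were dissociated and sorted for live cells carrying CD45, the surface marker of blood-derived cells. The tumour cells had received a guide RNA with a scrambled sequence (Scramble, 3 libraries) or a guide against the Notch ligand gene Jag2 (JAG2KO, 2 libraries). Droplet-based single-cell RNA sequencing gave 11063, 12391 and 10262 barcodes in Scramble libraries 1, 2 and 3, and 12706 and 21854 barcodes in JAG2KO libraries 1 and 2. Total counts were 93688591, 103246847 and 84788907 unique molecular identifiers (UMIs) in the Scramble libraries and 111680641 and 88782432 in the JAG2KO libraries. After filtering, 8742, 9502, 7563, 9450 and 17791 cells were kept in that order, with medians of 7606.5, 7548.5, 7684, 8420 and 2075 UMIs per cell. JAG2KO 2 therefore stood apart, with the most barcodes and the lowest depth per barcode. The series states that 10000 cells were encapsulated, without saying whether per library, and every library has more barcodes than that, JAG2KO 2 by the widest margin. Whether each of its barcodes, called cells here, holds a cell is therefore not known. The title of the series asks whether targeting Jagged2 in lung cancer alters anti-tumour immunity through Notch signalling and tumour-associated macrophages. The comparisons set JAG2KO against Scramble in cell type composition and, within cell types, in gene expression. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples. Gene symbols are those of the deposited gene table.

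Jag2 (ENSMUSG00000002799), the targeted gene, was low in the sorted cells of every library. It stood at 3.98, 3.13 and 4.29 CPM (counts scaled to the total of the library) in Scramble 1, 2 and 3, from 311, 264 and 294 UMIs. JAG2KO 1 and 2 had 3.41 and 2.25 CPM, from 309 and 154 UMIs. The 95% Poisson intervals, which cover counting error only, ran from 3.55 to 4.45, 2.77 to 3.54, 3.81 to 4.81, 3.04 to 3.82 and 1.91 to 2.64 CPM. In dendritic cells resembling cDC1 it stood at 20.4, 14.1 and 41.4 CPM in Scramble and 19.3 and 14.3 CPM in JAG2KO. Endothelial-like cells had 178 CPM in Scramble 1 and 111 CPM in Scramble 2, from 2 and 4 UMIs in 4 and 2 cells, 11.9 CPM in JAG2KO 2 and no UMI in Scramble 3 and JAG2KO 1. A fibroblast-like cluster led by Col3a1, Dcn and Rhox5, of cells that the sort for CD45 is meant to remove, had 1, 6 and 5 UMIs in Scramble (0.379, 1.33 and 1.10 CPM) and 3 and 0 UMIs in JAG2KO (0.386 CPM and up to 1.03 CPM). The sort is meant to remove the tumour cells in which the gene was targeted, and at these counts the levels do not check the labels.

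The JAG2KO libraries held more CD8 T-like cells, the class of killer T cells, and fewer neutrophil-like cells than the Scramble libraries. CD8 T-like cells made up 0.0276% ± 0.0145 of kept cells in Scramble (SD, n = 3) and 1.26% ± 0.837 in JAG2KO (SD, n = 2), a fitted difference of 44.2-fold (adjusted p = 1.41e-08, edgeR). The underlying cell numbers were 1, 3 and 3 in Scramble against 175 and 119 in JAG2KO. The size of the difference depends on a naming threshold for lymphoid sub-clusters that was set after seeing the data. With a lymphoid score of 0.3, the threshold of all other clusters, the share of CD8 T was 0.212% ± 0.059 in Scramble (SD, n = 3) and 1.98% ± 0.8097 in JAG2KO (SD, n = 2), 9.3-fold apart (adjusted p = 2.87e-05, edgeR). With a lymphoid score of 0.3 and no rule on leading genes, the share of CD8 T differed by 8.06-fold (adjusted p = 9.52e-05, edgeR). Neutrophil-like cells, short-lived phagocytes that include tumour-promoting forms, fell from 10.6% ± 1.08 (SD, n = 3) to 2.01% ± 0.689 (SD, n = 2), a fold of 0.189 (adjusted p = 0.00127, edgeR). Per 100 macrophage-like cells there were 15 ± 1.78 neutrophil-like cells in Scramble (SD, n = 3) and 3.28 ± 0.40 in JAG2KO (SD, n = 2). CD4 T-like cells, which carry helper functions, rose from 0.263% ± 0.0556 (SD, n = 3) to 0.762% ± 0.449 (SD, n = 2), 2.87-fold (adjusted p = 0.0399, edgeR). The exact two-sided permutation p was 0.1 for each of the 3 classes, the smallest that the 10 splits of 3 against 2 libraries allow. The CD8 and neutrophil calls held without any single library, with folds from 23.7 to 64.9 and from 0.143 to 0.235. The called share of CD4 T-like cells was lost without Scramble 1 (3.01-fold, adjusted p = 0.234), Scramble 2 (2.56-fold, adjusted p = 0.384) or Scramble 3 (3.11-fold, adjusted p = 0.152), and the fold moved to 1.70 without JAG2KO 1. With a lymphoid score of 0.3 the share of CD4 T was not called (2.26-fold, adjusted p = 0.102). With each library clustered separately, which named no CD4 T-like cells in Scramble, the share of CD4 T-like cells was not called either (adjusted p = 0.0942).

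**Figure D1:**
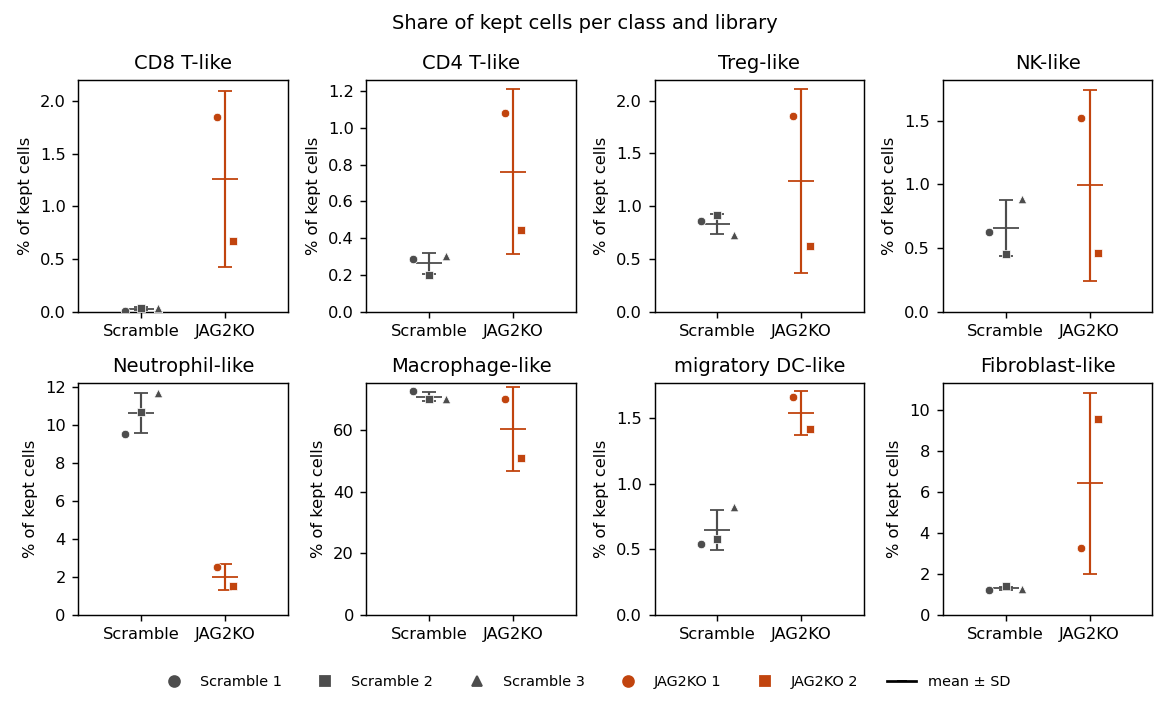
Share of kept cells (percent, vertical axis) in 8 cell classes for each library, with points for libraries and bars for the mean ± SD of 3 Scramble and 2 JAG2KO libraries. CD8 T-like cells lie at 1.85% and 0.669% in the JAG2KO libraries against at most 0.0397% in Scramble, and neutrophil-like cells at 2.50% and 1.52% against at least 9.53%.

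All shares are of cells sorted for CD45 and for exclusion of a dead-cell dye, so they say nothing about absolute numbers per tumour. Depth per cell differed between libraries, and 29.73% of the kept cells of JAG2KO 2 stayed unnamed. Cells with UMIs of Cd8b1 and of a Cd3 gene, counted without reference to clusters, were 0.110% ± 0.0223 of kept cells in Scramble (SD, n = 3) and 1.66% ± 0.611 in JAG2KO (SD, n = 2), 15.17-fold apart (exact permutation p = 0.1). After thinning each cell to 1000 UMIs the shares were 0.0543% ± 0.0138 and 0.881% ± 0.371, 16.23-fold apart. In this count 345, 639 and 430 shallower cells of Scramble and 438 and 3893 of JAG2KO were left out. As background, 0, 1 and 0 monocytes and macrophages of the Scramble libraries had both UMIs, and 7 and 32 of the JAG2KO libraries (0.102% and 0.346%), at median depths of 9399, 9532, 9182, 9562 and 4771.5 UMIs. Among the neutrophil-like cells, of median depth 1523, 1713, 1641, 1598.5 and 1083 UMIs, none had both, which allows shares of up to 0.3601%, 0.294%, 0.340%, 1.27% and 1.11%. Among lymphoid cells 5 sub-clusters stayed unnamed, together 0.846%, 1.19% and 0.952% of kept cells in Scramble and 2.88% and 1.06% in JAG2KO. The threshold set after seeing the data kept out 3 of them. The first of these 3, led by Xcl1 and Trbc2, held 0.252%, 0.116% and 0.185% against 0.698% and 0.736%. The sub-cluster led by Gzmc and Gzmb held 0.126%, 0.011% and 0.040% against 0.212% and 0.208%, and the one led by Ms4a4b and Gzmb 0.206%, 0.095% and 0.132% against 0.286% and 0.045%. The other unnamed sub-clusters, which also scored under 0.3, were led by Ikzf2 and Ms4a4b, with 0.229%, 0.916% and 0.542% against 1.60% and 0.051%, and by Nkg7 and Ctla4, with 0.034%, 0.053% and 0.053% against 0.085% and 0.022%. The sub-clusters led by Xcl1 and Trbc2 and by Gzmc and Gzmb scored highest as CD8 T cells, at 0.463 and 0.394. They had Cd8b1 at 109.6 and 229 CPM, against 868 CPM in the CD8 T-like cells, and a lymphoid score of 0.3 adds the first of them to that class. The second then stays out because markers of NK cells outnumber those of CD8 T cells among its leading genes, and joins without that rule.

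Fibroblast-like and endothelial-like cells, which a sort for CD45 is meant to remove, were also more frequent in JAG2KO, most of all in JAG2KO 2. Fibroblast-like cells, led by collagen genes, rose from 1.28% ± 0.0967 (SD, n = 3) to 6.42% ± 4.44 (SD, n = 2), 5.01-fold (adjusted p = 0.000852, edgeR), with 3.28% in JAG2KO 1 and 9.56% in JAG2KO 2. The fold was 2.55 without JAG2KO 2, and with each library clustered separately the share of Fibroblast-like cells was no longer called (1.73-fold, adjusted p = 0.217). A shallow cluster led by Col3a1, Col1a1 and Col1a2, of median depth 1620 UMIs, had 1617 of its 1817 cells, doublets included, from JAG2KO 2. The deeper cluster led by Col3a1, Dcn and Rhox5 held 70, 104 and 87 of the 8742, 9502 and 7563 kept cells of Scramble. In JAG2KO 1 and 2 this deeper cluster held 191 of 9450 and 130 of 17791 kept cells. The share of Endothelial-like cells was 0.0458%, 0.0211% and 0.0132% in Scramble and 0.0847% and 1.41% in JAG2KO, a fold of 26.9 (adjusted p = 0.000852, edgeR). It was no longer called without Scramble 3 (22.1-fold, adjusted p = 0.0856) or without JAG2KO 2 (3.02-fold, adjusted p = 0.095), and the fold was 40.7 without Scramble 1 and 49.96 without JAG2KO 1. It was not called with separate clustering (adjusted p = 0.327) or with a lymphoid score of 0.3 (26.9-fold, adjusted p = 0.083). The share of migratory DC-like cells, dendritic cells that carry antigen to lymph nodes, was 0.645% ± 0.152 in Scramble (SD, n = 3) and 1.54% ± 0.169 in JAG2KO (SD, n = 2), 2.39-fold, without passing the test (adjusted p = 0.0749, edgeR). The difference was 2.22-fold without JAG2KO 1 and 2.60-fold without JAG2KO 2. With 1 JAG2KO library left, the spread in a fit comes from the Scramble libraries alone. Smaller p-values or more called classes in such fits therefore add no support. Macrophage-like cells were the largest class at 72.7%, 70.2% and 70.2% in Scramble and 70.2% and 50.9% in JAG2KO (adjusted p = 0.749, edgeR). Regulatory T-like cells (0.834% and 1.24%, adjusted p = 0.443) and NK-like cells (0.656% and 0.992%, adjusted p = 0.443) did not pass, nor did monocyte-like cells (3.37% and 1.94%, adjusted p = 0.311). In all, 5 classes passed; 4, 4 and 3 passed without Scramble 1, 2 and 3, and 11 and 9 without JAG2KO 1 and 2. With a lymphoid score of 0.3, 3 of the shares of cells per class were called.

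The CD8 T-like cells of the JAG2KO libraries carried transcripts of killing and of activation. In JAG2KO 1 and 2, Gzmb (granzyme B) stood at 673 and 633 CPM, Prf1 (perforin) at 275 and 331 CPM, Ifng (interferon gamma) at 241 and 472 CPM, and Ccl5, a chemokine of effector T cells, at 6115 and 5987 CPM. The checkpoint receptor gene Pdcd1 stood at 326 and 422 CPM, and 41.7% and 66.4% of the cells had a UMI of it at median depths of 2722 and 2935 UMIs, against no neutrophil-like cell of these libraries. Lag3 stood at 50.8 and 159 CPM and Tox at 52.9 and 156 CPM, both known from exhausted T cells, and Tigit, another gene known from them, had no UMI in these 175 and 119 cells. At these depths this allows up to 1.71% and 2.52% of cells with a Tigit UMI and sets no limit on cells expressing the gene. Among genes known from naive and memory cells, Il7r stood at 198.8 and 177.2 CPM, Ccr7 at 61.3 and 57.3 CPM and Tcf7 at 14.8 and 7.8 CPM. With 7 CD8 T-like cells over the 3 Scramble libraries, gene expression in this class could not be compared between groups. B-like cells, with 9 to 11 cells per library, were not tested either.

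Monocytes and macrophages of the JAG2KO libraries had far less Spp1 and more Lpl than those of the Scramble libraries. Spp1 (ENSMUSG00000029304), which encodes the secreted glycoprotein osteopontin, fell from 3510 ± 646 CPM (SD, n = 3) to 680 ± 58.5 CPM (SD, n = 2), a log2 fold change of -2.37 ± 0.18 (SE; adjusted p = 0.00494, edgeR). Ccl12, a monocyte-attracting chemokine, fell from 434 ± 56.8 to 153 CPM (SD 4.998) (log2 -1.50 ± 0.13, adjusted p = 0.00686), and the Fc receptor-like gene Fcrls from 641 ± 14.7 to 216 ± 68.4 CPM (log2 -1.57 ± 0.19, adjusted p = 0.0211). Lpl (ENSMUSG00000015568), lipoprotein lipase, rose from 31.7 ± 4.58 to 141 ± 35.8 CPM (log2 2.15 ± 0.18, adjusted p = 0.00686), and Tnfaip2, a gene induced by tumour necrosis factor, from 61.1 ± 3.07 to 154 ± 22.5 CPM (log2 1.33 ± 0.11, adjusted p = 0.00686). Of 14151 genes tested, 146 rose and 158 fell; 2577 had an unadjusted p below the threshold of the test.

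Among the genes with the largest changes, the others that rose included Ccl17, a chemokine that attracts Ccr4-bearing T cells (log2 2.12), Adam19, a membrane metalloproteinase (1.79), Fbxo32, a ubiquitin ligase subunit (1.70), and Fxyd2, a sodium pump subunit (1.57). The surface receptor Slamf7 (1.23), Tns1, tensin (1.23), and Anpep, aminopeptidase N (1.14), were also among the 10 largest increases. The other decreases were Igfbp6, a binding protein of insulin-like growth factors (-2.09), Cbx6, a Polycomb protein (-1.84), Cd38, an enzyme that breaks down NAD (-1.70), Slc40a1, the iron exporter ferroportin (-1.60), Sh3bgrl2 (-1.50), Treml2 (-1.47) and Slfn4 (-1.40). Of all 14151 genes tested, 4870 had both JAG2KO libraries on the same side of all 3 Scramble libraries. The 20 genes did so by the naming rule, and their adjusted p-values ran up to 0.0444, for Cbx6. Some had levels far below those of another class: Ccl17 stood at 2.04% of its level in cDC2-like cells, Igfbp6 at 3.74% and Slfn4 at 2.83% of the levels in neutrophil-like cells, and Adam19 at 8.95% of that in CD8 T-like cells. Over all 304 called genes, 183 (60.2%) stood at 10% or more of their level in every other named class, and 181 (59.5%) when 8 unnamed clusters were also counted as classes. Levels given below as a share of another class are against named classes.

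**Figure D2:**
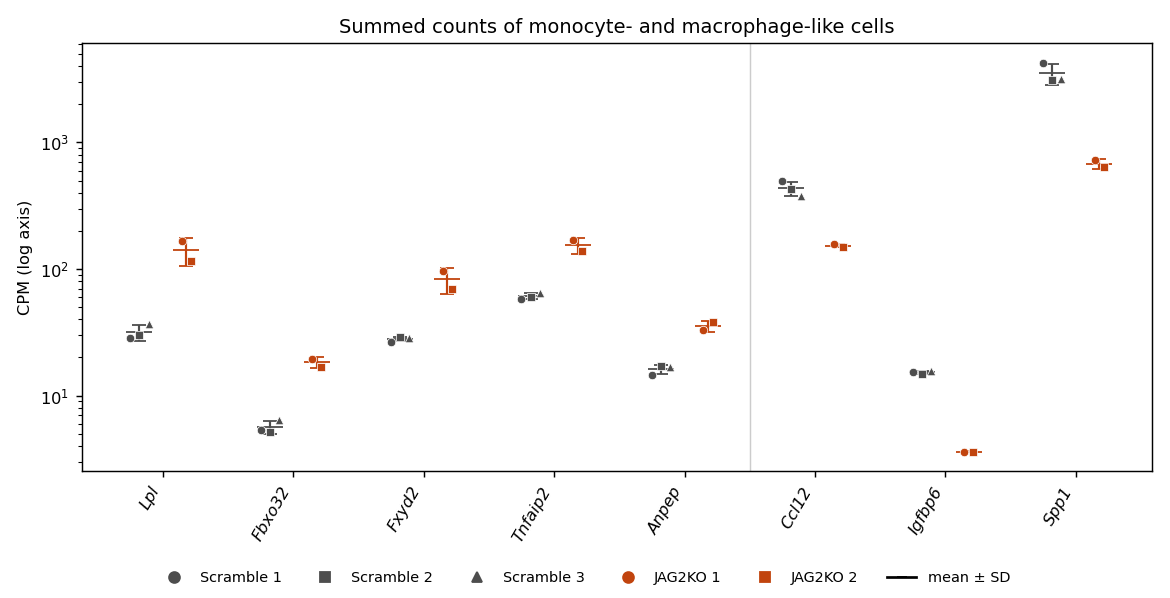
Level (CPM, log axis) of 8 genes among the largest called changes in monocytes and macrophages, those still called without any single library, with a point for each of 3 Scramble and 2 JAG2KO libraries. Spp1 lies near 3510 CPM in the Scramble mean and 680 CPM in the JAG2KO mean, and Lpl at 31.7 and 141 CPM.

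The calls depended on which libraries entered. Without Scramble 1, 37 genes passed, without Scramble 2 30, without Scramble 3 891, and without JAG2KO 2 79; without JAG2KO 1, 239 passed. Of the 20 genes above, Lpl, Fbxo32, Fxyd2, Tnfaip2, Anpep, Spp1, Igfbp6 and Ccl12 passed in all 5 of these fits. Without Scramble 2, 10 were lost (among them Ccl17, Adam19, Slamf7, Tns1, Cbx6, Cd38, Fcrls, Sh3bgrl2 and Slfn4, adjusted p up to 0.154), without Scramble 1 6 (among them Ccl17, Adam19, Cbx6, Cd38 and Fcrls, up to 0.105), without JAG2KO 2 6 (Slamf7, Cbx6, Slc40a1, Sh3bgrl2, Treml2 and Slfn4, up to 0.134) and without JAG2KO 1 3 (Slamf7, Cbx6 and Sh3bgrl2, up to 0.112). The cells of this class were spread differently over the clusters in the 2 groups. In Scramble they lay mainly in clusters led by Arg1 (18.2%, 17.4% and 21.4%), by F13a1 and Fcrls (16.2%, 16.7% and 17.8%) and by Fcrls, Gas6 and Ccl12 (17.5%, 15.9% and 13.2%). The same clusters, in that order, held 12.3%, 2.12% and 7.83% in JAG2KO 1 and 5.55%, 1.36% and 2.60% in JAG2KO 2. In JAG2KO 1 the cluster led by Cbr2 and C3ar1 held 24.4%. In JAG2KO 2 a cluster led by Iglc3, Retnla and Slc7a2, with over 90% of its cells from that library, held 37.0%. A cluster led by Retnla, Slc7a2 and Lpl held 9.85% and 16.2% in JAG2KO against 1.23%, 2.82% and 3.56% in Scramble. Without clusters drawn from a single library, 342 genes passed, and all 20 genes remained called. In macrophage-like cells alone 1 named call was lost, and in monocyte-like cells alone 19 were lost with their direction kept. At most 5% mitochondrial UMIs ended 13 of the 42 named calls, among them Ccl17, Cbx6, Slc40a1, Sh3bgrl2, Irf1 and Cd83 (adjusted p up to 0.0753). With no filter on low counts 4 were lost, among them Ccl17, Cbx6 and Slfn4 (up to 0.138). With each library clustered separately 14 of the 42 named calls were lost, among them Ccl17, Slc40a1, Irf4, Irf1, Il4ra and H2-K1 (adjusted p up to 0.418).

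Transcripts of other cells in this class also differed between the groups. The summed CD8 T markers stood at 3.4, 6.6 and 3.2 CPM in Scramble and 12 and 29.4 CPM in JAG2KO, and the immunoglobulin genes Igkc, Ighm and Jchain at 7.7, 15.6 and 9.6 against 20.2 and 176.1 CPM. Haemoglobin genes went the other way, from 340.4, 135.9 and 52.4 CPM to 13.4 and 6.2 CPM. The summed neutrophil markers stood at 376.9, 419.2 and 383.2 CPM against 305.7 and 342.1 CPM.

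Notch receptors and their nuclear partners showed no called change in monocytes and macrophages. Notch2 stood at 42.4 ± 4.52 CPM in Scramble (SD, n = 3) and 64.5 ± 11.5 CPM in JAG2KO (SD, n = 2), log2 0.60 (adjusted p = 0.0666, edgeR). Notch1 (41.7 and 43.9 CPM, adjusted p = 0.797), the DNA-binding partner Rbpj (485 and 529 CPM, adjusted p = 0.650), the target gene Hes1 (77.7 and 75.4 CPM, adjusted p = 0.953) and the ligand Jag1 (16.0 and 17.3 CPM, adjusted p = 0.679) lay within log2 0.12 of no change. In monocyte-like cells alone, a subset tested after the data were seen, Hes1 was called as higher in JAG2KO. Dll1 and Dll4 had too few counts to be tested. Of 27 measured members of the Notch list, 0 passed by edgeR over all genes, with 1 up and 1 down adjusted over the list alone, Notch2 and Notch4 having the smallest p-values. The median of the list was 0.01 and its mean -0.04, which differ in sign (camera, adjusted p = 0.744). Irf4, a transcription factor, rose from 4.09 ± 1.24 to 14.2 ± 3.14 CPM (log2 1.80 ± 0.25, adjusted p = 0.0317), at 8.94% of its level in B-like cells. The call was lost without Scramble 1 (adjusted p = 0.0714), Scramble 2 (0.120) or JAG2KO 2 (0.101). Arg1, arginase, stood at 1489 ± 191 and 939 ± 243 CPM (adjusted p = 0.108), the mannose receptor Mrc1 at 1165 and 879 CPM (0.296), the checkpoint ligand Cd274 at 23.7 and 35.0 CPM (0.218) and the T cell-attracting chemokine Cxcl9 at 84.6 ± 58.3 and 280.3 ± 29.97 CPM (0.262).

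The 24 gene lists were compared with all other genes by camera, and 17 were called in monocytes and macrophages, 11 up and 6 down. With an estimated correlation between genes 0 were called, and fry, a rotation test of each list by itself for a common direction, called 1. The mixed test of fry, in which members may move either way, passed for most lists. Among them were the Notch pathway (adjusted p = 0.0103, fry mixed) and alternative activation genes (0.00424). It did not pass for MHC class II (0.177), type I interferon (0.0779), cell cycle (0.467) or cytosolic ribosomal protein genes (0.482). MHC class II genes, which present antigen to CD4 T cells, rose as a list (median log2 1.10, adjusted p = 3.61e-06; adjusted p = 0.343 with an estimated correlation). Relative to the Scramble mean, the mean of the list lay at -0.443, 0.306 and 0.137 in Scramble 1, 2 and 3. In JAG2KO 1 the list lay close to Scramble 2, at 0.37, and in JAG2KO 2 it lay at 1.44. None of its 12 members passed by edgeR over all genes or adjusted over the list alone; H2-Ab1 stood at 937 ± 297 CPM in Scramble (SD, n = 3) and 2298 ± 1517 CPM in JAG2KO (SD, n = 2). Interferon gamma response genes rose (median 0.52, adjusted p = 5.73e-09; 0.343 with an estimated correlation), 2 of 25 over all genes, Irf1 (25.7 to 48.1 CPM) and Socs1 (5.87 to 10.6 CPM), and 7 up and 1 down adjusted over the list alone. Type I interferon response genes fell (median -0.58, adjusted p = 1.05e-15; 0.343 with an estimated correlation), with 0 of 31 called by edgeR over all genes and 17 down adjusted over the list alone, for example Ifit1 at 35.3 ± 5.36 and 17.6 ± 5.59 CPM. Its mean lay at -0.40 in JAG2KO 1 and -0.997 in JAG2KO 2. A cluster led by Fcgr1, Ifit2 and Ifit3 held 8.73%, 10.9% and 11.3% of monocytes and macrophages in Scramble and 4.4% and 1.33% in JAG2KO. The fall of the type I interferon list in the summed class therefore cannot by itself be told apart from the smaller share of this cluster. MHC class I genes rose (median 0.25, adjusted p = 0.000421; 0.368 with an estimated correlation), with H2-K1 called of 21 in both ways of adjusting. Dendritic cell maturation genes rose (median 0.59, adjusted p = 5.07e-08; 0.202 with an estimated correlation), 4 of 21 over all genes, among them Cd83 (151 to 300 CPM, log2 0.99) and Ccl22, at 0.137% of its level in migratory dendritic cells, and 10 up and 1 down adjusted over the list alone. Co-stimulation genes did not pass (15 members, adjusted p = 0.293), 0 by edgeR and 0 adjusted over the list alone, with Cd80 at 18.8 and 34.4 CPM.

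**Figure D3:**
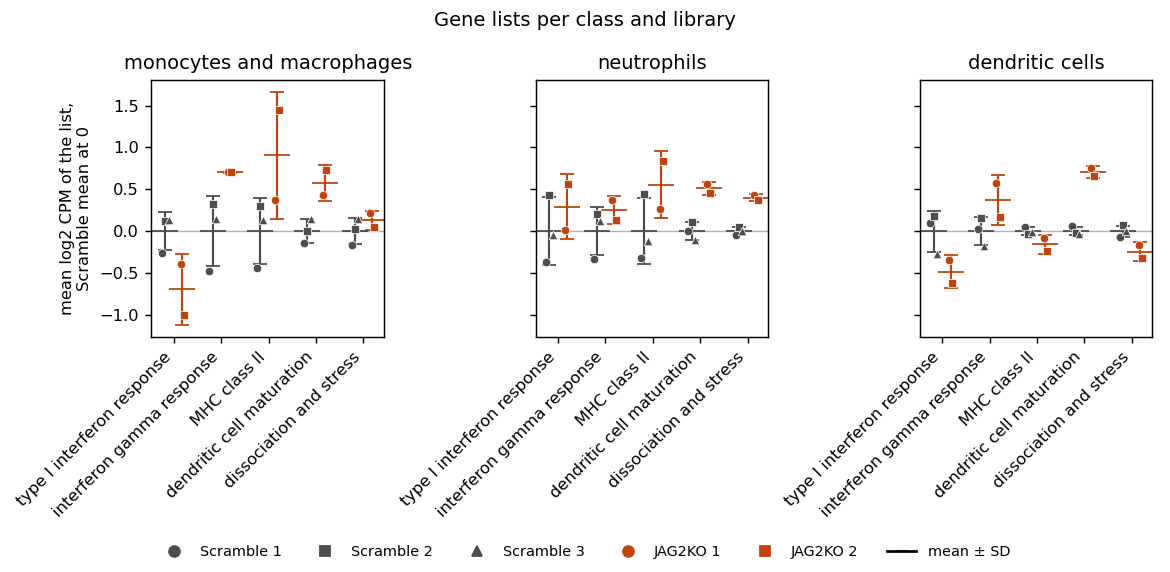
Mean log2 CPM of 5 gene lists relative to the Scramble mean (vertical axis, 0 is the mean of the Scramble libraries) in monocytes and macrophages, neutrophils and dendritic cells, with a point for each library. In monocytes and macrophages MHC class II lies at 0.37 and 1.44 in JAG2KO 1 and 2, and type I interferon genes at -0.40 and -0.997.

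Lipid handling genes rose (median 0.17, adjusted p = 9.31e-06; 0.202 with an estimated correlation), with 5 of 20 up over all genes and 9 up and 1 down adjusted over the list alone. Besides Lpl these included Pltp, a phospholipid transfer protein (431 to 730 CPM, log2 0.76), and Sqle, an enzyme of sterol synthesis (log2 0.89). Myeloid transcription factors rose (median 0.26, adjusted p = 6.73e-07; 0.343 with an estimated correlation), 3 of 33 over all genes, Irf4, Irf1 and the sterol sensor Nr1h3 (26.4 to 49.3 CPM, log2 0.90), and 10 up and 2 down adjusted over the list alone. Alternative activation genes did not move together (28 members, adjusted p = 0.297): Ccl17 and Ccl22 rose, Spp1 and the interleukin-4 receptor gene Il4ra (log2 -0.72) fell, and 8 up and 6 down passed adjusted over the list alone. Hypoxia and glycolysis genes fell (median -0.18, adjusted p = 0.000364; 0.343 with an estimated correlation), with Egln3, an oxygen sensor (log2 -0.98), called of 27 and 1 up and 8 down adjusted over the list alone. Complement and tissue macrophage genes fell (median -0.16, adjusted p = 0.00591; 0.280 with an estimated correlation), with the protease gene Ctsd called of 21 (1915 to 1312 CPM) and 2 down adjusted over the list alone. Monocyte genes did not pass (16 members, adjusted p = 0.0577), although Hp, haptoglobin, fell (log2 -0.91), with 2 up and 3 down adjusted over the list alone. Chemokines as a list did not pass (21 members, adjusted p = 0.664); Ccl17, Ccl22 and Ccl5 rose, Ccl12 and Cxcl14 (113 to 49.9 CPM) fell, and 5 up and 3 down passed adjusted over the list alone. The calls of Pltp, Irf1, Cd83, Socs1, Ebi3 and mt-Nd6 were lost without each of JAG2KO 1, JAG2KO 2, Scramble 1 and Scramble 2, and those of H2-K1, Ccl22, Il4ra, Hp, Nr1h3, Sqle, Ctsd, Xcl1, Serpinb6b, Ccl5 and Ctsw without each of JAG2KO 2, Scramble 1 and Scramble 2. Over the 42 named genes that were called, the highest lost adjusted p was 0.188. Cxcl14 was lost without JAG2KO 1, Scramble 1 or Scramble 2, Egln3 without JAG2KO 2, and Mmp8 without JAG2KO 1, JAG2KO 2 or Scramble 1. Ctsd and Mmp8 were also lost without Scramble 3 (adjusted p up to 0.0649).

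Lists of other cell types moved in monocytes and macrophages as well. Cytotoxicity genes rose (median 1.46, adjusted p = 3.25e-11; 0.280 with an estimated correlation), 5 of 23 over all genes and 14 adjusted over the list alone, with list means of 0.31 in JAG2KO 1 and 1.58 in JAG2KO 2. The called Xcl1, Ctsw, Ccl5 and Serpinb6b stood at 0.158% and 0.224% of their levels in NK-like cells and 0.474% and 0.118% of those in migratory dendritic cells. Without clusters drawn from a single library, Xcl1, Serpinb6b, Ccl5 and Ctsw were no longer called (adjusted p up to 0.110). T cell exhaustion genes (median 0.72, adjusted p = 3.22e-05; 0.346 with an estimated correlation), naive and memory T cell genes (0.79, adjusted p = 2.90e-05; 0.202 with an estimated correlation) and regulatory T cell genes (1.002, adjusted p = 3.61e-06; 0.202 with an estimated correlation) rose as lists, with 0 of 19, 0 of 15 and 1 of 17 members called by edgeR over all genes, and 2 up, 8 up and 1 down, and 4 up adjusted over the list alone. The mean of the exhaustion list lay at 0.36 in JAG2KO 1 and 0.98 in JAG2KO 2. The called regulatory T cell gene was Ebi3, a cytokine subunit (log2 0.64). Neutrophil maturation genes fell (median -0.65, adjusted p = 0.000421; 0.202 with an estimated correlation), and this was the list called by fry (adjusted p = 0.0494); Mmp8, at 4.39% of its level in neutrophil-like cells, was called of 13 and 2 down adjusted over the list alone, and the list means were -1.22 and -0.50 in JAG2KO 1 and 2. Tumour-associated neutrophil genes fell (median -0.17, adjusted p = 0.0043; 0.343 with an estimated correlation), with Spp1 called of 18 and 5 down adjusted over the list alone. Mitochondrially encoded genes rose (median 0.21, adjusted p = 0.000786; 0.343 with an estimated correlation), 1 of 13 over all genes, mt-Nd6 (log2 0.67), and 3 adjusted over the list alone. Cytosolic ribosomal protein genes fell slightly (median -0.09, adjusted p = 0.00808; 0.648 with an estimated correlation), 0 of 82 by edgeR over all genes and 0 adjusted over the list alone. Cell cycle genes (32 members, adjusted p = 0.356) and stress genes (20 members, adjusted p = 0.0695) did not pass, with 0 called in both ways of adjusting. The ribosomal call was lost without JAG2KO 1 (adjusted p = 0.923), and those of the exhaustion, tumour-associated neutrophil and mitochondrial lists without JAG2KO 2 (up to 0.153).

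Neutrophil-like cells of the JAG2KO libraries had less Nos2 and more Il1a, Ccl4 and Nr4a3. Nos2, inducible nitric oxide synthase, fell from 157 ± 28.0 CPM (SD, n = 3) to 25.8 ± 0.210 CPM (SD, n = 2), a log2 fold change of -2.60 ± 0.33 (SE; adjusted p = 1.36e-06, edgeR). Il1a, interleukin 1 alpha, rose from 74.0 ± 8.66 to 177 ± 0.665 CPM (log2 1.26 ± 0.23, adjusted p = 0.00141), the chemokine Ccl4 from 3584 ± 1189 to 8718 ± 1156 CPM (log2 1.28 ± 0.26, adjusted p = 0.00514) and Nr4a3, an immediate early transcription factor, from 133 ± 39.3 to 328 ± 71.8 CPM (log2 1.32 ± 0.23, adjusted p = 0.00121). Ptgs2, the prostaglandin enzyme COX-2 (log2 0.96, adjusted p = 0.0295), Tnf, tumour necrosis factor (1.04, adjusted p = 0.0476), and Nr4a1 (0.98, adjusted p = 0.0190) rose too. Of 7063 genes, 46 rose and 10 fell. The largest further changes were increases of Retnla (3.91 ± 3.50 to 58.9 ± 36.2 CPM), Il7r and Mllt6, at 8.73%, 0.324% and 8.48% of their levels in macrophage-like, gamma-delta T-like and migratory dendritic cells, and decreases of Cstdc5, a stefin-like gene (log2 -2.53), and Ntpcr (-2.16). The macrophage genes Msr1 (log2 -1.62) and Ccl12 (-1.88) fell in this class, beside summed macrophage markers of 3436.5, 4508.4 and 3217.3 CPM in Scramble and 3006.1 and 1830.4 CPM in JAG2KO, and summed CD8 T markers of 17.0, 35.3 and 14.7 against 68.4 and 63.4 CPM. The 2 JAG2KO libraries held 236 and 271 of these cells against 833, 1019 and 883 in Scramble.

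In neutrophil-like cells 15 of 24 lists were called, and none with an estimated correlation. Tumour-associated neutrophil genes rose (median 0.40, adjusted p = 6.91e-10; 0.214 with an estimated correlation), with 4 of 18 over all genes, Il1a, Ccl4, Ptgs2 and Tnf, and 7 adjusted over the list alone. Co-stimulation and stimulatory cytokines rose (median 0.70, adjusted p = 1.29e-10; 0.0774 with an estimated correlation), 2 of 11 over all genes and 6 adjusted over the list alone. Stress genes rose (median 0.47, adjusted p = 2.56e-09; 0.0774 with an estimated correlation), with 0 of 20 by edgeR over all genes and 7 adjusted over the list alone. Type I interferon genes rose (median 0.34, adjusted p = 6.41e-06; 0.469 with an estimated correlation), 1 of 28 over all genes, Rsad2 (531 ± 138 to 978 ± 119 CPM), and 3 adjusted over the list alone. The call of the list was lost without JAG2KO 2 (adjusted p = 0.937). Interferon gamma response genes rose (median 0.47, adjusted p = 0.0239; 0.423 with an estimated correlation), with Ifi47 up and Nos2 down of 19 over all genes and 4 up and 1 down adjusted over the list alone, and this call was lost without Scramble 1 (adjusted p up to 0.538 among lost lists) or JAG2KO 1 (up to 0.658). Cytotoxicity genes rose (median 1.16, adjusted p = 4.21e-12; 0.0907 with an estimated correlation), 3 of 8 over all genes, Ccl4, Tnf and Xcl1, the last at 0.667% of its level in NK-like cells, and 7 adjusted over the list alone. Mitochondrially encoded genes rose (median 0.43, adjusted p = 3.40e-05; 0.214 with an estimated correlation), with 0 of 12 by edgeR over all genes and 1 adjusted over the list alone. Their list means were 0.433 and 0.432 in JAG2KO 1 and 2 against -0.086, 0.196 and -0.11 in Scramble. The other called lists that rose were MHC class II, MHC class I, myeloid transcription factors, T cell exhaustion, naive and memory T cell and dendritic cell maturation genes (adjusted p up to 0.0352; at least 0.0907 with an estimated correlation). Over all genes 0 of 7, 0 of 21, 2 of 29, 2 of 12, 1 of 9 and 0 of 11 of their members were called by edgeR, and 2, 0, 2, 2, 2 and 6 adjusted over the list alone. Complement and tissue macrophage genes and hypoxia and glycolysis genes fell (adjusted p = 2.66e-06 and 0.0172; 0.261 and 0.632 with an estimated correlation), with 0 of 20 and 0 of 26 by edgeR over all genes and 3 and 0 adjusted over the list alone. MHC class I was lost without Scramble 1, JAG2KO 1 or JAG2KO 2, MHC class II without JAG2KO 2, naive and memory genes without JAG2KO 1 or JAG2KO 2, and hypoxia genes without Scramble 1 or JAG2KO 1. Neutrophil maturation genes did not pass (15 members, median 0.06 and mean -0.30, which differ in sign; adjusted p = 0.932). With each library clustered separately 10 of the 17 named calls were lost, those of Ntpcr, Rsad2, Ifi47, Tnf, Msr1, Nr4a1, Nr4a3, Ccl4, Ptgs2 and Xcl1 (adjusted p up to 0.284). Among cells of at least 1000 UMIs and 500 genes 8 were lost, those of Il7r, Cstdc5, Ntpcr, Rsad2, Ifi47, Tnf, Nr4a1 and Ptgs2 (up to 0.135). By DESeq2 the lost calls were those of Ntpcr, Ifi47 and Tnf of 13 tested (up to 0.1695). The number of called genes was 33 without Scramble 2, 22 without Scramble 3 and 99 without JAG2KO 2, and 53 and 79 without Scramble 1 and JAG2KO 1. Nos2, Il1a, Ccl12 and Nr4a3 passed in all 5 of these fits, whereas without JAG2KO 1 Retnla, Il7r, Mllt6, Cstdc5, Ntpcr, Ifi47, Tnf, Nr4a1, Ptgs2 and Xcl1 were lost (adjusted p up to 0.997). Tnf, Nr4a1, Ccl4 and Ptgs2 were also lost without Scramble 2 and without Scramble 3 (adjusted p up to 0.2999). Rsad2 and Ifi47 were lost without Scramble 3 and without JAG2KO 2 (up to 0.168 in the latter), Ptgs2 and Rsad2 without Scramble 1 (up to 0.183), Il7r without each of the 5 libraries, and Ntpcr without Scramble 2 and without Scramble 3.

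Dendritic cells of the JAG2KO libraries, pooled over their subsets, had more transcripts of maturation and fewer of the type I interferon response. Ccl22, a chemokine of mature dendritic cells, rose from 496 ± 33.7 CPM (SD, n = 3) to 1140 ± 123 CPM (SD, n = 2), log2 1.2 ± 0.13 (SE; adjusted p = 2.495e-05, edgeR). The actin bundler Fscn1 rose from 348 ± 19.6 to 618 ± 20.1 CPM (log2 0.83 ± 0.13, adjusted p = 0.00069), the lymph node homing receptor Ccr7 from 424 ± 63.9 to 778 ± 175 CPM (log2 0.88 ± 0.15, adjusted p = 0.00241) and Socs2 from 97.3 to 167 CPM (log2 0.78, adjusted p = 0.00353). Irf7, a driver of type I interferon, fell from 94.6 ± 23.5 to 42.0 ± 8.01 CPM (log2 -1.13 ± 0.20, adjusted p = 0.00455), as did Slfn5 (-0.92), Ifi44 (-1.31) and Isg20 (-0.997). Of 9331 genes, 101 rose and 54 fell. The largest changes of genes at 10 CPM or more were increases of Clu, clusterin (13.5 to 39.9 CPM, log2 1.60), Gbp4 (1.44) and Mir155hg, the host gene of a microRNA of activated leukocytes (1.39), and decreases of Snx22, a cDC1 marker (-1.56), Apoc2 (-1.51) and the macrophage gene Fcrls (-1.41). The mix of subsets differed: migratory cells were 20.3% ± 2.44 of dendritic cells in Scramble (SD, n = 3) and 46.2% ± 18.3 in JAG2KO (SD, n = 2), cDC1-like cells 22.9% ± 2.25 and 14.7% ± 0.21, and cDC2-like cells 56.8% ± 2.93 and 39.2% ± 18.1, each with an exact permutation p of 0.1. Summed migratory markers stood at 2558.5, 2889.8 and 2546.2 CPM against 4845 and 5692.3 CPM. Ccl22, Fscn1, Ccr7 and Socs2 are themselves among the markers by which migratory cells were named. Their rise in the pooled class therefore cannot by itself be told apart from the larger migratory share. The maturation list holds these genes and the migratory markers Ccl5 and Il4i1. When subsets were tested alone, after the data were seen, 35 genes passed in cDC1-like cells, 46 in cDC2-like cells and 0 in migratory cells by edgeR. With their direction kept, 15 named calls were lost in cDC1-like cells alone and 20 in cDC2-like cells alone, and none held in migratory cells.

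Of 24 lists, 14 were called in dendritic cells, and none with an estimated correlation. By fry, for a common direction, only the maturation list was called (adjusted p = 0.0398). The maturation list rose (median 0.79, adjusted p = 5.95e-31; 0.0548 with an estimated correlation), with 12 of 21 members up over all genes and 18 adjusted over the list alone, among them the ligand of PD-1 Cd274 (log2 0.59) and Cd80 (0.62). It rose in cDC1-like cells alone (adjusted p = 1.17e-07; 0.219 with an estimated correlation) and cDC2-like cells alone (3.03e-08; 0.154 with an estimated correlation) but did not pass in migratory cells (0.964). Type I interferon genes fell (median -0.43, adjusted p = 1.36e-11; 0.237 with an estimated correlation), 4 of 29 over all genes and 9 adjusted over the list alone, and they fell in cDC1-like cells alone (adjusted p = 1.35e-46; 0.157 with an estimated correlation) without passing in cDC2-like (0.0505) or migratory cells (0.823). Interferon gamma response genes rose (median 0.43, adjusted p = 5.02e-06; 0.285 with an estimated correlation), 7 of 21 over all genes, for example Gbp4, Gbp2 (log2 0.80) and Irf1 (0.73), and 7 up and 1 down adjusted over the list alone. In cDC1-like cells alone the list fell (adjusted p = 0.008; 0.436 with an estimated correlation). It rose in cDC2-like cells alone (9.77e-05, and 0.575 with an estimated correlation) and in migratory cells alone (0.000345, and 0.978 with an estimated correlation). Stress genes fell (median -0.25, adjusted p = 2.34e-06; 0.237 with an estimated correlation), 3 of 20 over all genes, the heat shock genes Dnajb1 (log2 -0.72) and Hspa1a (-0.53) and Jun (-0.62), and 7 adjusted over the list alone. The stress list fell in cDC2-like cells alone (adjusted p = 2.78e-12, and 0.217 with an estimated correlation). In cDC1-like cells alone it rose (0.0177, and 0.551 with an estimated correlation), and in migratory cells it did not pass (0.964). MHC class II genes fell (median -0.16, adjusted p = 0.0102; 0.335 with an estimated correlation), 0 of 12 by edgeR over all genes and 1 up and 2 down adjusted over the list alone, a call lost without JAG2KO 2. The MHC class II list passed in no subset alone. It pointed down in cDC1-like (adjusted p = 0.558) and cDC2-like cells (0.585) and up in migratory cells (0.914). The regulatory T cell list rose (median 0.53, adjusted p = 4.49e-06; 0.237 with an estimated correlation), 3 up and 1 down of 13 over all genes and 7 up and 1 down adjusted over the list alone, with its markers Il2ra and Tnfrsf4 at 4.37% and 1.74% of their levels in regulatory T-like cells. Chemokines rose in the test (adjusted p = 0.0242; 0.277 with an estimated correlation) with a median of 0.11 and a mean of -0.003, which differ in sign, 3 of 18 over all genes and 6 up and 3 down adjusted over the list alone. The call was lost without Scramble 2, Scramble 3 or JAG2KO 2 (adjusted p up to 0.497). Cell cycle genes rose (median 0.29, adjusted p = 1.90e-06; 0.207 with an estimated correlation), 1 of 32 over all genes and 2 adjusted over the list alone. Their list means were 0.325 and 0.233 in JAG2KO 1 and 2 against -0.046, 0.013 and 0.034 in Scramble. Mitochondrially encoded genes rose too (median 0.195, adjusted p = 0.00234; 0.237 with an estimated correlation), 0 of 13 by edgeR over all genes and 1 adjusted over the list alone. Their list means were 0.263 and 0.199 against 0.088, -0.056 and -0.032. Co-stimulation, cytotoxicity and naive and memory T cell genes rose (adjusted p up to 0.00874; at least 0.207 with an estimated correlation), with 2 of 14, 3 of 11 and 2 of 13 over all genes and 5, 5 and 3 adjusted over the list alone. Complement and tissue macrophage genes and neutrophil maturation genes fell (adjusted p up to 0.0132; at least 0.237 with an estimated correlation), with 1 of 21 and 1 of 5 over all genes and, adjusted over the list alone, 1 up and 4 down and 1 down. The means of the complement list were -0.442 and 0.161 in JAG2KO 1 and 2, which differ in sign, against -0.03, 0.181 and -0.151 in Scramble. Complement genes were lost without Scramble 2 or JAG2KO 1, naive and memory genes without JAG2KO 1, and both with separate clustering. Retnla (log2 3.71) and the killer cell gene Nkg7 (3.29) rose at 6.04% and 0.201% of their levels in macrophage-like and CD8 T-like cells. The number of called genes was 101, 102 and 154 without Scramble 1, 2 and 3, 157 without JAG2KO 1 and 250 without JAG2KO 2. Ccl22, Fscn1, Ccr7, Socs2, Clu, Mir155hg, Snx22 and Irf7 passed in all 5 of these fits. With each library clustered separately 27 of the 41 named calls were lost, among them Fscn1, Ccr7, Gbp4, Slfn5, Irf1, Cd80, Cd274, Fcrls, Jun, Hspa1a and Retnla (adjusted p up to 0.968). With doublets kept, and with doublets removed by the automatic threshold, 12 of the 41 were lost, among them Cd80, Cd274, Apoc2, Hspa1a, Pdcd1lg2 and Ccl17 (up to 0.3596). By DESeq2 16 of 36 were lost, among them Cd80, Cd274, Gbp2, Irf1, Ifi44, Isg20 and Tnfrsf4 (up to 0.331). Over the 41 named genes that were called, 15, 16 and 5 were lost without Scramble 1, 2 and 3 and 14 and 10 without JAG2KO 1 and 2, with adjusted p up to 0.684; among the genes above, Apoc2 was lost without Scramble 1, Scramble 3 or JAG2KO 1, and Gbp2 and Irf1 without Scramble 1 or JAG2KO 1. Ifi44, Cd80 and Cd274 were lost without Scramble 1, Scramble 2 or JAG2KO 1, and Isg20 without Scramble 1, JAG2KO 1 or JAG2KO 2. Jun was lost without Scramble 2 or JAG2KO 2, Hspa1a without any of Scramble 2, Scramble 3, JAG2KO 1 and JAG2KO 2, and Tnfrsf4 without JAG2KO 1. The interferon gamma list was lost without JAG2KO 1 (adjusted p up to 0.240 among lost lists).

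In CD4 T cells, taken here with regulatory T-like cells, 3 genes rose and 8 fell of 5341. Ramp3, a receptor-modifying protein, rose from 53.2 ± 23.2 CPM (SD, n = 3) to 151 ± 22.1 CPM (SD, n = 2), log2 1.52 ± 0.29 (SE; adjusted p = 0.0175, edgeR), the granzyme inhibitor Serpinb9 from 34.6 to 93.8 CPM (log2 1.40, adjusted p = 0.0471) and the homing receptor Ccr7 from 106 to 236 CPM (log2 1.201, adjusted p = 0.0270). The named decreases were Ccl12 (78.5 to 7.85 CPM), Spp1 (417 to 40.6 CPM) and Ccl3 (102 to 22.3 CPM), with Thbs1, Arg1 and Ier3, genes of myeloid cells, beside summed macrophage markers of 2079.3, 2725.8 and 1905.9 CPM in Scramble and 1488.9 and 513.2 CPM in JAG2KO. Regulatory T-like cells made up 75.9% ± 5.85 of these cells in Scramble (SD, n = 3) and 60.7% ± 3.54 in JAG2KO (SD, n = 2, exact permutation p = 0.1). The increases in the pooled class therefore cannot by themselves be told apart from this difference in mix. Without Scramble 2, 0 genes passed by edgeR and all of the named calls were lost (adjusted p up to 0.529), and without JAG2KO 1 72 passed. Without Scramble 1 6 of the 9 named calls were lost (up to 0.253), without Scramble 3 2 (up to 0.158) and without JAG2KO 2 3 (up to 0.178). With separate clustering 7 of the 9 were lost, and those of Ramp3 and Ccl12 remained (adjusted p of lost calls up to 0.854). Of 23 lists, 8 were called and none with an estimated correlation (adjusted p of at least 0.155 with an estimated correlation); 6 fell and 2 rose. The lowest medians were those of chemokines (-1.125) and alternative activation genes (-0.96). Those that rose were cytosolic ribosomal protein genes (median 0.31, adjusted p = 2.24e-14; 0.466 with an estimated correlation) and mitochondrially encoded genes (0.14, adjusted p = 0.0365; 0.466 with an estimated correlation). Of their members 0 of 80 and 0 of 12 were called by edgeR over all genes and 0 adjusted over the list alone. The ribosomal list means were 0.134 and 0.451 in JAG2KO 1 and 2 against 0.307, -0.073 and -0.234 in Scramble. The mitochondrial call was lost without each of Scramble 2, Scramble 3, JAG2KO 1 and JAG2KO 2 (adjusted p for list mitochondrially encoded in CD4 T cells up to 0.2205). When subsets were tested alone, after the data were seen, 0 genes passed by edgeR in CD4 T-like cells. Scramble 2, with 19 of these cells, was left out there. In CD4 T-like cells alone 7 named calls were lost with their direction kept, and in regulatory T-like cells alone 4. In the whole class 306 genes had an unadjusted p below the threshold, and DESeq2 called 6. By DESeq2 the increases of Ramp3, Serpinb9 and Ccr7 and the decreases of Thbs1 and Ier3 were not called (adjusted p up to 0.7498). Ramp3 and Serpinb9 were also lost among cells of at least 1000 UMIs and 500 genes (6 of the 9 calls, adjusted p up to 0.146) and at 5% mitochondrial UMIs (6 of the 9, up to 0.159).

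In NK-like cells edgeR called 0 of 4487 genes, with 159 at an unadjusted p below the threshold, and DESeq2 called 0. The smallest p-values were those of Ccdc88a (93.6 ± 31.4 CPM in Scramble, n = 3, and 33.9 ± 4.59 CPM in JAG2KO, n = 2), Ier5l (88.1 and 196 CPM) and Sgpl1 (75.5 and 26.7 CPM), each with an adjusted p of 0.761. Without Scramble 3, 7 genes passed, and without JAG2KO 1 and 2 25 and 7. Of 22 lists 6 were called, none with an estimated correlation (adjusted p of at least 0.415 with an estimated correlation), and cytotoxicity genes were not among them. Complement, hypoxia and lipid handling genes fell, and tumour-associated neutrophil, ribosomal protein and mitochondrially encoded genes rose (adjusted p up to 0.0309), with 0 members by edgeR over all genes and, adjusted over the list alone, 1 down each for hypoxia and lipid handling. Each of the 6 calls was lost without at least 1 library. The ribosomal list means, 0.013 and 0.286 in JAG2KO 1 and 2, lay within the Scramble range of -0.226 to 0.328. In JAG2KO 1 the complement (-0.017) and tumour-associated neutrophil (0.118) means also lay within that of Scramble, against -1.258 and 0.738 in JAG2KO 2. Mitochondrial means were 0.378 and 0.191 against 0.191, -0.143 and -0.048. For hypoxia and lipid handling both JAG2KO means lay below all Scramble means.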

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

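Of the tests in this part, those of lymphocyte RNA, of shallow cells in JAG2KO 2 and of CD8 T cells missed by the naming were chosen before the result was seen, and all others after it.

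In monocytes and macrophages 304 genes differed between JAG2KO and Scramble, Spp1, Ccl12 and Lpl among them. Shallow cells of JAG2KO 2 as the whole cause are argued against by JAG2KO 1: when JAG2KO 2 was set against 2 Scramble libraries, 88.1%, 89.9% and 79.5% of the called genes lay on the same side in JAG2KO 1 relative to the Scramble library left out. Free RNA from other cell types stays open for most called genes: 60.2% stood at 10% or more of their level in every other named class, but only 13.5% (41 genes) had their highest level in this class, or 4.3% (13 genes, Ccl12 and Cxcl14 among them) when unnamed clusters also counted, some of which were richer in Spp1, Fcrls and Lpl. For the called cytotoxicity genes 0.0 of 5 reached that level, and free RNA from lymphocytes cannot be told apart from that of other cells, since among named classes Xcl1 and Ctsw were highest in NK-like cells but Ccl5 and Serpinb6b in migratory dendritic cells. The JAG2KO tumour cells as the biological explanation, and the processing day, the dissociation and the size of the tumours, were untested.

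CD8 T-like cells were more frequent in JAG2KO libraries, by a fold that the naming moves from 44.2 to 9.3 in the share of CD8 T with a lymphoid score of 0.3. As the whole cause, cells of the Scramble libraries missed by the naming would have closed the gap among cells with Cd8b1 and Cd3 UMIs, but after thinning these were still 16.23-fold more frequent in JAG2KO. Barcodes of JAG2KO 2 as the cause are argued against by JAG2KO 1, whose share has a lower limit of 1.59%. JAG2KO tumour cells may have drawn in or kept more of these cells, which was not tested, and the processing day and tumour size stay open as well.

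Neutrophil-like cells were less frequent in JAG2KO libraries. Barcodes of JAG2KO 2 as the cause are argued against by the share in JAG2KO 1, with an upper limit of 2.832%. Growth of classes other than macrophages is argued against by at most 3.56 neutrophil-like per 100 macrophage-like cells in JAG2KO, against at least 13.1 in Scramble. Loss of shallow neutrophil-like cells below the depth limit cannot be told apart by the fold of 0.179 among cells of at least 1000 UMIs and 500 genes, since a higher limit removes more of them. The JAG2KO tumour cells, the dissociation, the processing day and tumour size stay open, all untested.

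Among monocytes and macrophages, neutrophils and dendritic cells, the only classes searched, some lists were called in opposite directions. Both JAG2KO libraries lay on the same side of the Scramble mean within a class and on the other side in another, and the lists were chosen for this. In neutrophils JAG2KO 1 lay within the Scramble range for type I interferon genes (0.015 against -0.375 to 0.426) and MHC class II (0.27 against -0.325 to 0.439). All of these calls are lost with an estimated correlation, and the smallest p of the exact permutation test is 0.1, so no difference between classes was shown. The JAG2KO minus Scramble difference in mean log2 CPM of MHC class II was higher by 1.064 in monocytes and macrophages than in dendritic cells (p = 0.1, exact). For MHC class II in neutrophils minus dendritic cells the value was 0.715 (p = 0.3, exact), and both list calls were lost without JAG2KO 2. For stress genes in neutrophils minus dendritic cells it was 0.642 (p = 0.1, exact). For tumour-associated neutrophil genes in monocytes and macrophages minus neutrophils it was -0.745, and for type I interferon genes -0.986 (both p = 0.1, exact). For type I interferon genes in neutrophils minus dendritic cells it was 0.775 (p = 0.1, exact).

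Among cells outside the named classes, clusters led by Acp5 and Ctsk held 2.275% of kept cells in JAG2KO 1 and 2.012% in JAG2KO 2, above the 0.343%, 0.189% and 0.291% of the Scramble libraries. In JAG2KO 2 most of these cells (1.428% of kept cells) lay in a cluster drawn almost wholly from that library, of median depth 1156 UMIs. Unnamed cells made up 29.73% of the kept cells of JAG2KO 2, most of them in a cluster led by Igkc, Jchain and Hbb-bs with a median of 851 UMIs.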

How the results depend on the processing

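Chosen only after the result was seen were the tests on subsets of classes alone, without clusters drawn from 1 library, with a lymphoid score of 0.3 and with named immune cells as the total, and the alternatives for named genes and lists outside monocytes and macrophages. Of the named genes under all alternatives, 6733 values kept direction and side of the threshold, 93 changed direction without a call in either fit, 481 lost the call, 316 gained it and 15 reversed with a call. For lists these were 1089, 104, 176, 71 and 12, and for shares 192, 9, 18, 18 and 1. The 9 uncalled shares that changed direction were, without JAG2KO 1, the share of gamma-delta T (0.707), the share of NK (0.715), the share of pDC (0.849) and the share of Treg (0.738). They were also the share of cDC1 (1.031) without JAG2KO 2, the share of B (1.061) and the share of cDC2 (1.055) with separate clustering, and the share of cDC2 (1.01) and the share of Macrophage (1.057) with named immune cells as the total. The neutrophil and CD8 T shares lost their call in no fit that left out a library. With a lymphoid score of 0.3, also with no rule on leading genes, the shares of cells per class called numbered 3, with folds of 2.26 in the share of CD4 T and 26.947 and, without that rule, 26.944 in the share of Endothelial cells, both no longer called (adjusted p from 0.0805 to 0.108). Unless stated, the cause was not tested. CD8 T-like and B-like cells gave no gene test in any fit. On simulated data 2-fold changes were recovered less often than 4-fold changes in every class tested.

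The genes changed in monocytes and macrophages numbered 1149 by the DESeq2 Wald test, 695 with no filter on low counts, 143 at 5% mitochondrial UMIs, 143 with separate clustering and 70 in monocyte-like cells alone. In neutrophils they numbered 29 among cells of at least 1000 UMIs and 500 genes. In dendritic cells they numbered 76 (Wald), 299 (no filter), 43 (separate clustering), 35 (cDC1-like alone), 46 (cDC2-like alone) and 0 (migratory DC-like alone). In CD4 T cells they numbered 6 (Wald), 35 (no filter), 3 (at least 1000 UMIs and 500 genes), 5 (5% mitochondrial), 6 (separate), 1 (genes under 10% of their level in another class left out), 0 (CD4 T-like alone) and 5 (Treg-like alone), and in NK cells 12 (no filter) and 2 (5% mitochondrial). With an estimated correlation 0 gene lists in monocytes and macrophages were called, and by fry for a common direction 1.

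Replicate numbers are shared between the groups, with nothing else to pair them, and log2 changes within the pairs correlated at 0.143 and 0.130. With the replicate block the genes changed in monocytes and macrophages numbered 1755, in CD4 T cells 39 and in NK cells 12. It lost the calls of the shares of Endothelial, CD4 T, Fibroblast and Neutrophil cells and kept that of CD8 T cells, so that 1 class was called, with folds of 12.666 in the share of Endothelial, 2.901 in the share of CD4 T, 4.345 in the share of Fibroblast and 0.193 in the share of Neutrophil cells. Among named genes it lost the calls of Il7r, Tnf, Nr4a1, Ccl4 and Ptgs2 in neutrophils, Apoc2, Pdcd1lg2, Lrrc32 and Hspa1a in dendritic cells, Serpinb9 in CD4 T cells and Slfn4 in monocytes and macrophages. With separate clustering 2 classes were called by share, those of CD8 T and Neutrophil cells, and the others lost their call. The Scramble libraries then held no Endothelial, CD4 T or CD8 T cells, so the fitted folds of 761.372 in the share of Endothelial and 1030.149 in the share of CD4 T cells measure no size and are no bounds. The fold in the share of Fibroblast cells was 1.732. The share of Endothelial cells was 33.071-fold among cells of at least 1000 UMIs and 500 genes and 35.763-fold at 5% mitochondrial UMIs.

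Reversed values in monocyte-like cells alone were 0.782 for Hes1 in monocytes and macrophages, -0.666 for Nr1h3 in monocytes and macrophages and -0.148 for Pltp in monocytes and macrophages (log2). In dendritic cells Fcrls was 0.436 with separate clustering, and in cDC1-like cells alone Irf1 was -0.141 and Hspa1a 0.016. In migratory DC-like cells alone Slfn5 was 0.378, Il15ra -0.028, Pdcd1lg2 -0.003, Ccl17 -0.011, Cd274 -0.089, Serpinb9 in dendritic cells -0.132, Fscn1 -0.082, Socs2 -0.114 and Pclaf in dendritic cells -0.587. With separate clustering these reversed: list lipid handling in neutrophils (adjusted p = 0.008965), list cytosolic ribosomal proteins in neutrophils (0.0001559), list hypoxia and glycolysis in CD4 T cells (0.004733), list dissociation and stress in CD4 T cells (0.01306) and list cell cycle in NK cells (6.444e-22).

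With 1 library left out, called genes ranged from 30 to 891 in monocytes and macrophages, 22 to 99 in neutrophils, 101 to 250 in dendritic cells, 0 to 72 in CD4 T cells and 0 to 25 in NK cells, and called classes from 3 to 11. Folds ranged from 1.702 to 4.129 in the share of CD4 T, 3.017 to 49.96 in the share of Endothelial and 0.354 to 1.448 in the share of cDC2 cells, the latter reversed without JAG2KO 2. Adjusted p ranged from 8.356e-09 to 0.9233 for list cytosolic ribosomal proteins in monocytes and macrophages, 0.0003962 to 0.7915 for list neutrophil maturation in neutrophils and 2.208e-16 to 0.9372 for list type I interferon response in neutrophils. It ranged from 8.609e-11 to 0.2056 for list complement and tissue macrophage in dendritic cells, 0.01264 to 0.8228 for list myeloid transcription factors in CD4 T cells, 0.04813 to 0.7011 for list T cell exhaustion in NK cells and 1.391e-05 to 0.7011 for list cytotoxicity in NK cells. Each of these lists changed direction in at least 1 of these fits.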

Other observations

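The comparison of the Acp5 and Ctsk clusters was chosen after the result was seen, as was Retnla below. The cells led by Acp5 and Ctsk, which encode an acid phosphatase and a collagen-degrading protease known from osteoclasts, lay in 2 clusters. The first, of median depth 14056 UMIs, held 0.343%, 0.179% and 0.291% of kept cells in Scramble and 2.22% and 0.585% in JAG2KO, with means of 0.271% ± 0.084 (SD, n = 3) and 1.403% ± 1.16 (SD, n = 2; exact permutation p = 0.1). The second, of median depth 1156 UMIs, held 254 cells (1.43%) of JAG2KO 2 and 5 cells (0.053%) of JAG2KO 1, against 1 cell of Scramble 2 and none of Scramble 1 and 3, which allows up to 0.0343% and 0.0397%. The values below are over both clusters. Acp5 stood at 7579.51, 4334.37 and 6672.54 CPM in these cells of the Scramble libraries and 5802.95 and 4978.12 CPM in JAG2KO, against 40.89 to 95.77 CPM in monocytes and macrophages. In the same cells Ctsk stood at 2313.99 to 5629.7 CPM. Atp6v0d2, a proton pump subunit, stood at 423.72 to 703.98 CPM and Ocstamp, a gene of cell fusion, at 124.77 to 228.26 CPM.

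Retnla, a secreted protein of alternatively activated macrophages, was chosen after its values were seen. In monocytes and macrophages it stood at 23.8 ± 11.2 CPM in Scramble (SD, n = 3) and 282 ± 193 CPM in JAG2KO (SD, n = 2), log2 3.57 ± 0.61, without passing the test (adjusted p = 0.0702, edgeR). Per library it stood at 19.2, 15.6 and 36.6 CPM in Scramble and 418 and 146 CPM in JAG2KO. An unnamed cluster led by haemoglobin genes held 5.58%, 5.53% and 3.90% of kept cells in Scramble and 2.20% and 0.259% in JAG2KO.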
